A study of Mus musculus with 95 samples.

How the data were processed

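The deposited table holds a single value per gene and library on a log2 scale, variance-stabilised and batch corrected by the authors per the labels. Per the submitters' processing notes, cutadapt, STAR 2.5.2b, Salmon and DESeq2 were used with the mm9 build. The notes give no role or order for these tools, and the tool behind the batch correction is not given in the sources used here. Reads were not analysed here, and no step upstream of the deposited values was redone. The labels' protocol text describes another experiment, so the library kit and the dissection were not taken from it.

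The table held 24444 genes in 95 libraries, of which 3485 genes had the same value in every library and were set aside, leaving 20959 genes tested. Values ran from 1.34 to 20, and 1.567 was the floor given to a gene with no reads. Normalised counts were obtained by inverting the curve v = log2(K + n/2 + sqrt(n^2 + 4Kn)/2), in which n is the count and K is 2 to the power of the floor. Values under the floor were set to a count of 0. Reads in genes ranged from 7.4 to 42.9 M per library with a median of 25.8 M, estimated from the spacing of the lowest values.

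Libraries were named by genotype (WT, HOM, MATHET, PATHET), age (E14.5, 1mo, 6mo, 12mo) and replicate number. Replicates 1 to 3 carried the first library batch (47 libraries) and replicates 4 to 6 the second (48 libraries). Each of the 16 groups held 6 libraries, except WT at E14.5 with 5. The labels give no sex and do not say whether the libraries of a group came from separate animals, so p-values measure the spread between libraries.

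Each gene was fitted with limma 3.58.1 in R 4.3.3 with data.table (1.17.8) with 16 group means and a batch term, and variances were moderated with a trend on the mean. The residual degrees of freedom were 78 and the prior degrees of freedom 3.84. Adjusted p-values were Benjamini and Hochberg values over the 20959 genes, with 0.05 as the threshold. Log2 differences are given with the moderated standard error, and the number of libraries on the side of the difference refers to the mean of the reference group. The genotype-by-age interaction was a moderated F test over 9 contrasts.

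Gene lists were fixed before the data were examined and tested with the limma function camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Lists with fewer than 5 measured genes were not tested, which left 34 of 36 lists. Each list was also tested with the correlation estimated from the data, which widens the null when genes of a list vary together, and with the rotation test fry. Members of a list were counted past 0.05 after adjustment over all genes and after adjustment over the list alone.

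The rule for naming genes was fixed before the data were examined. For a genotype contrast it took Ube3a, the 10 largest rises and the 10 largest falls past adjusted p 0.05, and up to 4 members of each list past 0.05 over the list alone. Where fewer than 5 genes passed, the 5 smallest p-values were taken and said not to pass. For an age step in WT it took Ube3a, the 5 largest changes each way and up to 2 members of each list. For the interaction it took the 10 smallest p-values. Genes on the sex chromosomes that separate males from females were not named among changed genes, and Xist was read per library only as a check.

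Alternatives fixed before the data were examined were a model without the batch term, each batch alone, only the libraries of an age or only WT libraries, and quantile normalization. The others were removal of the lowest 25% of genes, the replicate number as a block, Xist and Y genes as covariates, and each library left out in turn. Alternatives added after the results were seen were a correction for RNA of another age, removal of 2 libraries with a trend on transcript length, and removal of that trend from all libraries. An average over 6mo and 12mo only and the mean of the glucocorticoid list as a covariate were added at the same point. The correction for RNA of another age estimated a share per library from 31 genes high after birth and 42 high at E14.5. Those genes had a minimum count of 1000 after birth or 500 at E14.5 and at most 1% of it at the other age. The 45 genes of late expression had a count over 200 and under 0.5% of it at E14.5, so the sets can share genes. A change of such a gene after the correction is no separate test of it. Transcript lengths came from GENCODE vM21 and were matched by gene name, since its build differs from that of the submitters.

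Detection was measured in simulated libraries with independent noise per gene, by adding known differences to a contrast with few real calls and refitting. Overlaps between mutants that share the WT libraries were set against 20 simulations in which only the shared WT libraries linked the contrasts. These held no genotype effect, and their noise was independent between genes. Counts were set against 100 splits of the same libraries in which the labels of the groups compared were exchanged, within age for averages and the interaction. The random seed was 1.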

Results

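Cerebral cortex of mice carrying a missense allele of Ube3a, which the series title links to autism and describes as gain of function, was compared with wild-type (WT) cortex at 4 ages. Ube3a encodes an E3 ubiquitin ligase, is imprinted, and is expressed in neurons mostly from the maternal copy. Homozygous (HOM) mice and heterozygous mice that inherited the allele from the mother (MATHET) or from the father (PATHET) were analysed at E14.5, 1 month (1mo), 6 months (6mo) and 12 months (12mo). The 95 libraries formed 16 groups of 6, except WT at E14.5 with 5, in 2 library batches that each held 3 libraries of nearly every group. Gene lists, contrasts and the rule for naming genes were fixed before the data were examined. The labels do not say whether the libraries of a group came from separate animals, so p-values measure spread between libraries. Differences are log2 differences with the standard error from limma, levels are means with the SD of normalised counts, and adjusted p-values cover 20959 genes unless a list is named.

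Libraries held 7.4 to 42.9 M reads in genes with a median of 25.8 M. The smallest group mean was 19.2±5.5 M in WT at 12mo and the largest 31.5±5.7 M in WT at 1mo. The lowest correlation between 2 libraries of a group was 0.9721, over genes with a mean value above 5, and no 2 libraries of a group were identical. Replicates with the same number were not more alike across groups than others, with a mean r of -0.0037 over 141 pairs, so libraries were not paired. Detection was measured in simulated libraries with WT means in every mutant and independent noise at the fitted spread of each gene. Known differences were added there to HOM at 6mo, in genes with a mean value over 5. Of these 22 of 67 were found at a log2 difference of 0.25, 59 of 67 at 0.5 and 65 of 66 at 1. There were 5 false calls among 151. Error that genes share in the real libraries was not simulated.

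Ube3a itself did not change with genotype at any age. At E14.5 its level was 12.17±0.08 in WT (n = 5), 12.15±0.07 in HOM, 12.16±0.10 in MATHET and 12.11±0.13 in PATHET (n = 6 each). At 1mo WT stood at 11.66±0.06 and PATHET at 11.56±0.20, the largest difference from WT, at -0.10±0.06 (95% interval -0.22 to 0.02, adjusted p = 0.35). Between MATHET and PATHET at 1mo the difference was 0.11 with an interval of -0.0059 to 0.23. Both differences include PATHET replicate 3, at 11.2 against 11.6 to 11.7 in the other libraries of its group. At 6mo the groups lay between 11.63±0.16 in WT and 11.71±0.05 in HOM, and at 12mo between 11.65±0.11 in MATHET and 11.72±0.04 in PATHET. Differences averaged over ages were 0.02±0.03 in HOM, 0.02±0.03 in MATHET and -0.01±0.03 in PATHET. In WT, Ube3a fell from 4610±260 normalised counts at E14.5 to 3230±130 at 1mo, a log2 difference of -0.51±0.06 (limma adjusted p = 1.24e-11, 6 of 6 libraries), and it did not change at the later steps.

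**Figure D1:**
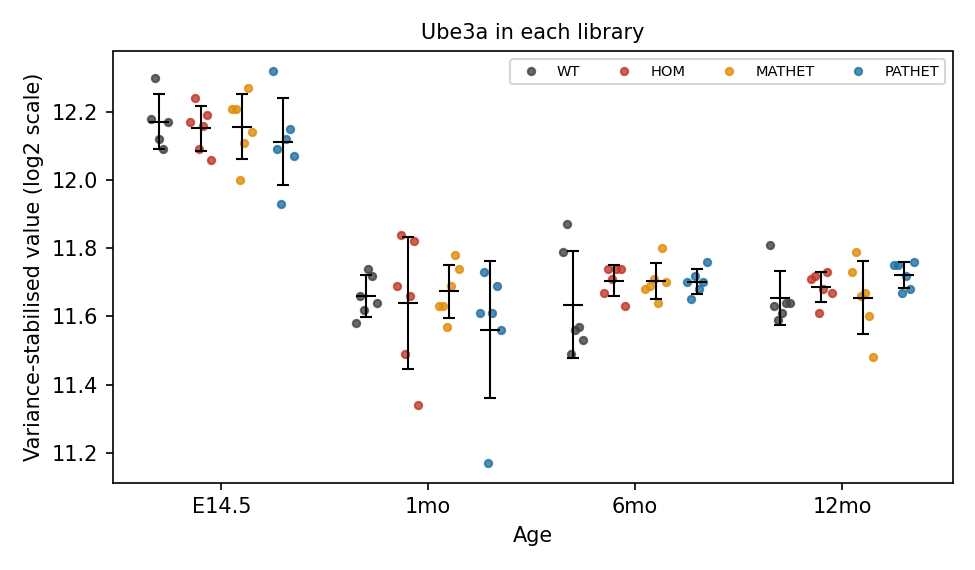
Ube3a in each library by age and genotype on the deposited log2 scale.

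From E14.5 to 1mo the WT cortex gained transcripts of glia and mature neurons. Mobp, a myelin protein gene, rose from 4.32±0.9 to 8310±1200 counts, a log2 difference of 9.82±0.14 (limma adjusted p = 9.33e-72, 6 of 6 libraries). Gpr37l1 rose by 9.22±0.13, the astrocyte filament gene Gfap by 8.75±0.19, Mag by 8.73±0.14 and Fam107a by 8.42±0.13. The embryonic globins Hbb-y and Hba-x fell by 7.09±0.47 and 6.24±0.33. Igf2bp1 fell by 6.52±0.27, and Eomes and Neurog2, transcription factors of cortical progenitors, fell by 6.28±0.66 and 5.99±0.26. In all, 7571 genes rose and 7118 fell.

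All 23 measured myelin genes rose between these ages (median 5.40, camera adjusted p = 3.49e-16, and 0.012 with an estimated correlation), as did 16 of 18 astrocyte genes (median 3.5, 2.34e-09 and 0.011). Of 26 cell cycle genes 25 fell, with Top2a at -5.84±0.22 (list median -4.86, 5.34e-14 and 0.044). All 21 GABA receptor and synapse genes rose, among them Gabrd by 6.23±0.13 and Gabra1 by 6.18±0.14 (median 2.52, camera adjusted p = 1.74e-10, 0.08 with an estimated correlation). All 24 glutamate receptor and synapse genes also rose, with Camk2a at 6.43±0.08 (median 2.51, 6.81e-12, and 0.14 with an estimated correlation). Of 32 genes of mature interneurons 28 rose, with Lamp5 at 7.78±0.16 and the calcium-binding protein gene Pvalb at 7.75±0.24 (4.99e-08, 0.057 with an estimated correlation). Genes of interneuron development moved the other way in 19 of 30 members, with Nkx2-1 at -4.99±0.31 (0.0183, 0.29 with an estimated correlation). Of 23 progenitor genes 19 fell (median -2.36, 4.95e-06, 0.13 with an estimated correlation), and all 40 ribosomal protein genes fell (median -1.40, 3.49e-16, 0.2 with an estimated correlation). Among imprinted genes H19 fell by 5.86±0.26, Peg12 fell by 5.06±0.26 and Rasgrf1 rose by 6.53±0.15.

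**Figure D2:**
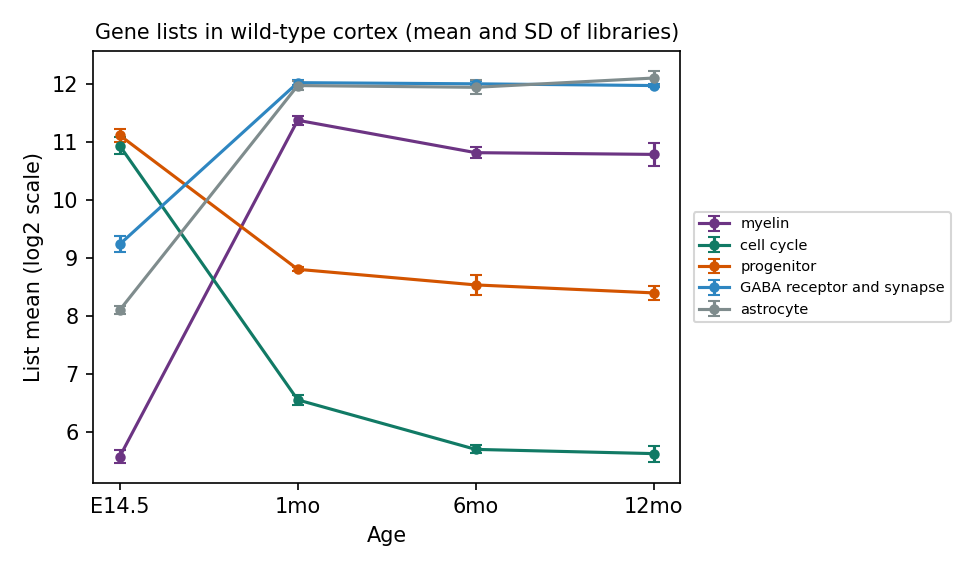
Means and SD of 5 gene lists in WT libraries at the 4 ages.

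From 1mo to 6mo in WT, transcripts of dividing cells and of the embryo fell. Top2a fell by 2.44±0.21 (limma adjusted p = 1.33e-15), Mki67 fell by 2.07±0.17, Igfbpl1 fell by 2.76±0.22 and H19 fell by 2.44±0.25, each in 6 of 6 libraries. The cytokine gene Il33 rose by 1.82±0.14 (adjusted p = 6.03e-19), Rpe65 by 1.98±0.21 and Abca8a by 1.83±0.15. The step held 1048 rises and 1476 falls. Of 26 cell cycle genes 16 fell over all genes and 18 over the list alone (median -0.81, camera adjusted p = 6.61e-20, 0.014 with an estimated correlation). Myelin genes fell in 11 of 23 members, 13 over the list alone (median -0.48, 4.37e-17 and 0.014), with Enpp6, a gene of newly formed oligodendrocytes, at -1.58±0.14. Oligodendrocyte precursor genes fell in 5 of 12, 7 over the list alone, with Gpr17 at -1.60±0.17. Immediate early genes fell in 13 of 22, 15 over the list alone (median -0.84, 3.43e-09, 0.22 with an estimated correlation), and ribosomal protein genes rose in 22 of 40, 30 over the list alone (median 0.20, 4.15e-16, 0.39 with an estimated correlation). WT libraries at 1mo held a larger share of embryonic transcripts than the other libraries of that age, 1.79% to 2.63% against 1.08% to 1.51%. After correction for it Top2a, WT 6mo vs 1mo, lay at -1.36, Mki67 at -1.24, Igfbpl1 at -1.5 and H19 at -0.84 (adjusted p = 0.13), 8 cell cycle genes fell (median -0.28, adjusted p = 0.34 with an estimated correlation), and Hbb-y lay at 0.89. Within batches 1015 and 1068 genes passed.

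Between 6mo and 12mo in WT, genes that glucocorticoids induce rose together. Plin4 rose from 34±9.6 to 567±190 counts (3.81±0.37, limma adjusted p = 8.68e-13) and Lcn2, a secreted siderophore-binding protein gene, from 3.35±3.1 to 176±120 (4.54±0.66, 3.79e-07), each in 6 of 6 libraries. The serpin gene Serpina3f rose by 3.14±0.41, the endothelial adhesion gene Sele by 2.56±0.44, Sgk1 by 1.76±0.17 and the clock gene Per2 by 1.15±0.13. The largest falls were Adh1 at -1.48±0.30, Alox12 at -1.45±0.21 and Myct1 at -1.37±0.21. All 14 glucocorticoid genes rose (median 0.99, camera adjusted p = 2.8e-36, 2.1e-08 with an estimated correlation), as did all 16 heat shock genes (median 0.40, 3.57e-20 and 0.0098), with Hspa1b at 1.52±0.26. Of 22 immediate early genes 12 rose, 16 over the list alone, with Fosb at 1.37±0.21 (median 0.65, 1.18e-12, 0.095 with an estimated correlation). Endothelial genes fell in 8 of 16, with Cldn5, a tight junction gene, at -0.90±0.13, and rose in 2, with the glucose transporter Slc2a1 at 1.00±0.11 (0.0176, 0.76 with an estimated correlation). The step held 1211 rises and 1012 falls, and within batches 316 and 1337 genes passed.

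In HOM cortex at E14.5, few genes differed from WT. Gabrb2, a GABA-A receptor subunit gene, fell from 1610±390 to 897±340 counts (-0.91±0.19, limma adjusted p = 0.0251, 6 of 6 libraries). The histone gene Hist1h2ag fell by 0.95±0.16 (adjusted p = 0.000646, 5 of 6 libraries) and the receptor gene Vipr1 fell by 0.54±0.11 (5 of 6). Atp13a4 rose by 0.78±0.13 (adjusted p = 0.000646), Kcnj16 by 0.87±0.18, L3mbtl1 by 0.92±0.20 (5 of 6), and Crhr1, a receptor for corticotropin-releasing hormone, from 63.4±8.6 to 92.4±26 counts (0.48±0.10, 0.0251). Sowahb rose by 0.90±0.16 near the floor of the scale. Across 45 genes of late expression, chosen on WT libraries for low values at E14.5, 34 lay above WT in HOM, with a median excess of 0.0773% of their mean WT level at 6mo and 12mo. Sowahb and Kcnj16 were among the 45. The WT libraries that chose these genes were also the reference, which favours an excess in any other group. In all 8 genes rose and 4 fell, and 1831 had an unadjusted p under 0.05. Lists of GABA receptor and synapse genes (median 0.16, camera adjusted p = 8.06e-07, 0.36 with an estimated correlation) and cell cycle genes (median -0.27, 7.97e-09, 0.36 with an estimated correlation) passed at the preset correlation only. Only 1 of 21 GABA receptor and synapse genes passed over all genes, and 3 passed over the list alone. Within batches 9 and 601 genes passed, none passed when only E14.5 libraries were fitted, and without HOM replicate 1 the count was 111.

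In MATHET cortex at E14.5, transcripts of postnatal glia stood above WT. Mobp rose from 4.32±0.9 to 24.4±8.2 counts (1.67±0.14, limma adjusted p = 2.82e-15), Gpr37l1 by 1.29±0.13 (6.07e-12), Mag by 1.21±0.14 (4.83e-09) and Gfap from 5.74±4.5 to 19.1±8.7 counts (1.23±0.19, 1.77e-05), each in 6 of 6 libraries. The interneuron gene Pvalb rose by 1.05±0.24 (0.0171), the myelin gene Plp1 by 0.82±0.10 and the neuronal gene Nrgn by 0.69±0.14. Among the falls, Ccdc34os at -0.99±0.17, Smr3a at -0.86 and Vsig4 at -0.55 all lay near the floor. The totals were 39 rises and 4 falls, with 1001 genes at an unadjusted p under 0.05. Myelin genes rose in 7 of 23 members, 9 over the list alone with 1 fall (median 0.21, camera adjusted p = 9.49e-26, 0.00083 with an estimated correlation). Astrocyte genes rose in 3 of 18 (3.46e-05, 0.14 with an estimated correlation) and mature interneuron genes in 1 of 32, 4 over the list alone (median 0.07, 0.00048, 0.36 with an estimated correlation). The same direction held in both batches for Mobp, at 1.48 and 1.85. Of the 45 late genes, chosen for low values in the WT libraries that are also the reference, all lay above WT. Their median excess was 0.241% of their mean WT level at 6mo and 12mo. After the correction for RNA of another age, which estimates a share per library from genes that can overlap with these 45, 9 genes passed. That share ran from 0.513% to 0.877% in MATHET and from 0.354% to 0.514% in WT libraries at E14.5. In HOM libraries at E14.5 it was 0.316% to 0.364% in batch 1 and 0.572% to 0.712% in batch 2, the latter within the range of MATHET. When only E14.5 libraries were fitted 1 gene passed.

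PATHET cortex at E14.5 held a larger set of the same kind. Mobp rose to 36.3±17 counts (2.12±0.14, limma adjusted p = 4.32e-21), Gpr37l1 by 1.89±0.13 (9.72e-21), Gfap by 1.88±0.19 and Mag by 1.57±0.14, each in 6 of 6 libraries. Ptgds, a prostaglandin D synthase gene, rose from 133±35 to 394±200 counts (1.44±0.28). Pvalb rose by 1.38±0.24 (4.08e-05), Lamp5 by 1.08±0.16 and Vip by 0.97±0.18, all markers of mature interneuron types. The transcription factor genes Pitx2 and Tfap2b rose by 2.24±0.70 (0.0438) and 2.04±0.62 (0.038) in 5 of 6 libraries, Tfap2b to 904±1400 counts from 73.3±8.3. Shisa2 fell from 1410±210 to 968±110 counts (-0.54±0.17, 0.0479) and Slc16a3 fell by 0.56±0.17 (5 of 6). There were 753 rises and 279 falls.

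By list, 14 of 23 myelin genes rose in PATHET at E14.5, 18 over the list alone (median 0.65, camera adjusted p = 6.87e-29, 3e-04 with an estimated correlation). Mature interneuron genes rose in 10 of 32, 16 over the list alone (median 0.24, 6.58e-10 and 0.034), precursor genes in 4 of 12, 8 over the list alone (0.038 with an estimated correlation), and astrocyte genes in 7 of 18 with 1 fall (0.023 with an estimated correlation). GABA receptor and synapse genes rose in 13 of 21, 17 over the list alone (median 0.37, 4.9e-12, 0.054 with an estimated correlation), with Gabra1 at 0.84±0.14. Glutamate receptor and synapse genes rose in 11 of 24, 17 over the list alone (median 0.31, 1.6e-13, 0.12 with an estimated correlation), with Camk2a at 0.58±0.08. Of 26 cell cycle genes 5 fell, 14 over the list alone, with Mcm5 at -0.44±0.12 (median -0.37, 6.25e-12, 0.058 with an estimated correlation). The chromosome 7 domain that holds Ube3a had 3 rises among 19 genes, namely Gabra5 at 0.45±0.13 (0.0271), Gabrb3 at 0.28±0.08 (0.0348) and Ndn at 0.37±0.11 (0.0402), and the list as a whole did not pass (0.152). Other imprinted genes rose in 7 of 40, 11 over the list alone with 2 falls, with Rasgrf1 at 1.15±0.15 (0.00116, 0.27 with an estimated correlation). Of the 45 late genes all lay above WT, with a median excess of 0.571% of their mean WT level at 6mo and 12mo. The list values above were not corrected for RNA of another age. After that correction Camk2a lay at -0.01 and Lamp5 at -0.54.

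Mobp in PATHET at E14.5 stood above WT in both batches, at 2.41 and 1.82. After the correction for RNA of another age 518 genes passed (288 higher and 230 lower). Gpr37l1 then lay at -0.13, Lamp5 at -0.54 and Camk2a at -0.01. With only E14.5 libraries 26 genes passed, within batches 496 and 138, without WT replicate 1 the count was 369, without WT replicate 2 it was 437, and without PATHET replicate 5 it was 496.

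**Figure D3:**
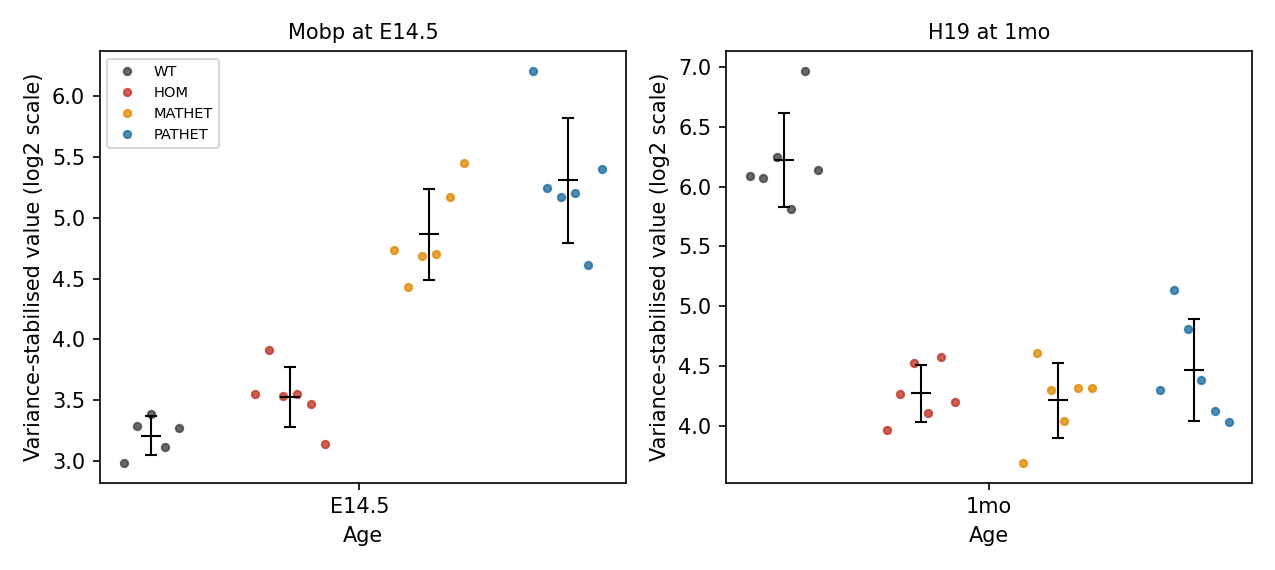
Mobp at E14.5 and H19 at 1mo in each library, with mean and SD of each group.

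At 1mo, HOM cortex differed from WT in many genes of small size and in a set of embryonic transcripts. H19, an imprinted non-coding RNA, fell from 71.2±24 to 14.1±3.2 counts (-1.94±0.25, limma adjusted p = 5.26e-08), Igf2bp1 fell by 1.69±0.26, Hbb-y fell by 1.76±0.45 and Igfbpl1 fell from 174±23 to 55.2±12 counts (-1.57±0.22), each in 6 of 6 libraries. Smim3 rose from 192±16 counts by 0.99±0.15 (3.49e-06), Tsc22d3, a glucocorticoid-induced gene, by 0.77±0.12 (1.56e-05), Cdkn1a by 0.83±0.16 and Pglyrp1 by 0.84±0.16. The pituitary hormone gene Prl rose to 53.2±89 counts from 1.43±1.3 (2.33±0.67, 0.0164). Totals were 1271 rises and 781 falls.

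Ribosomal protein genes rose in 22 of 40 members in HOM at 1mo, 38 over the list alone, with Rpl37 at 0.32±0.07 (median 0.21, camera adjusted p = 4.09e-21, 0.24 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose in 25 of 28, 27 over the list alone, with Ndufb3 at 0.27±0.05 (median 0.20, 1.14e-19, 0.15 with an estimated correlation). Proteasome genes rose in 20 of 40, 27 over the list alone, with Psmc5 at 0.24±0.05 (median 0.17, 9.47e-17, 0.24 with an estimated correlation). Heat shock genes rose in 8 of 16, 11 over the list alone, with Hspa5 at 0.74±0.14 and Hspa8 at 0.43±0.07 (1.96e-11, 0.15 with an estimated correlation), and glucocorticoid genes in 4 of 14, 7 over the list alone (2.54e-06, 0.15 with an estimated correlation). Cell cycle genes fell in 5 of 26 with 1 rise, with Mki67 at -0.93±0.17 (5.65e-05, 0.42 with an estimated correlation). Nipa2, in the chromosome 7 domain, rose by 0.23±0.05 (0.00207) and Magel2 fell by 0.96±0.31 (0.0313). Among reported Ube3a substrates 4 of 24 rose (0.0421, 0.35 with an estimated correlation), namely Psmc5, Psmb1 at 0.23±0.06, Rhoa at 0.18±0.05 and Kcnn2 at 0.27±0.08. Choroid plexus genes fell in 3 of 18, 9 over the list alone (median -1.17, 2.24e-05, 0.45 with an estimated correlation). HOM replicate 6 stood apart from the other libraries of its group by a slope of its values on transcript length of -0.263, against -0.0685 to 0.0257. With it and PATHET replicate 3 left out, 9 ribosomal protein, 12 proteasome and 12 oxidative phosphorylation genes rose in HOM. Without it 835 genes passed, with only 1mo libraries 448, and within batches 16 and 1938.

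In MATHET cortex at 1mo, H19 fell by 2.00±0.25 (limma adjusted p = 2.88e-08), Hbb-y fell by 2.23±0.45, Igf2bp1 fell by 1.99±0.26 and Igfbpl1 fell by 1.34±0.22. Btg2 fell from 914±310 to 314±86 counts (-1.48±0.30, 0.00403) and the activity-regulated transcription factor genes Npas4, Junb and Nr4a1 fell by 1.43±0.36, 1.17±0.24 and 1.12±0.27. Homer1, a postsynaptic scaffold gene, rose from 5820±470 to 8430±1400 counts (0.52±0.11, 0.00423), Smim3 by 0.61±0.15 (0.0221) and Cdkn1a by 0.60 (5 of 6 libraries). Gabrb2 fell by 0.74±0.19 (0.0302). Totals were 43 rises and 118 falls, with 2353 genes at an unadjusted p under 0.05. Immediate early genes fell in 7 of 22 with 1 rise, and over the list alone in 11 with 3 rises (median -0.40, camera adjusted p = 1.18e-06, 0.27 with an estimated correlation). Cell cycle genes fell in 3 of 26, 10 over the list alone (median -0.38, 7.69e-11, 0.21 with an estimated correlation). None of 18 meningeal and fibroblast genes passed over all genes and 13 fell over the list alone (median -0.57, 4.81e-11, 0.21 with an estimated correlation). After correction for the larger share of embryonic transcripts in WT libraries 87 genes passed, Hbb-y lay at -0.18, H19 at -0.77 (adjusted p = 0.41), Igf2bp1 at -0.30, Igfbpl1 at -0.28, Top2a at 0.11 and Neurog2 at 0.09, while Btg2, MATHET vs WT at 1mo, lay at -1.46 (adjusted p = 0.015). Within batches 17 and 62 genes passed, with only 1mo libraries 93, and leaving out MATHET replicate 4 left 77.

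In PATHET cortex at 1mo, H19 fell to 17.4±7.2 counts (-1.75±0.25, limma adjusted p = 1.67e-06), Igf2bp1 fell by 1.99±0.26 (2.01e-07), Igfbpl1 fell by 1.37±0.22 and Col2a1, a cartilage collagen gene, fell by 1.34±0.17. Mki67 fell by 1.10±0.17 (7.63e-06) and Nkx2-1, a transcription factor gene of the ganglionic eminence, fell by 1.07±0.29 (0.0208). Of the choroid plexus list, Prlr lay at -1.32±0.38 (0.0295), Clic6 at -1.28±0.39 (0.0359) and Kl at -1.15±0.35 (0.0372). Folr1 lay at -1.58±0.56 and did not pass over all genes (0.0732). The clock gene Cry1 rose by 0.55±0.10, Sdf2l1 by 0.68±0.18 and 9230104L09Rik by 1.71±0.32 (5 of 6 libraries). Totals were 687 rises and 504 falls. Oxidative phosphorylation genes rose in 17 of 28, 27 over the list alone (median 0.19, camera adjusted p = 1.59e-20, 0.27 with an estimated correlation). Ribosomal protein genes rose in 13 of 40, 30 over the list alone (median 0.18, 2.04e-19, 0.38 with an estimated correlation), and proteasome genes in 13 of 40, 30 over the list alone with 1 fall (median 0.16, 7.27e-18, 0.27 with an estimated correlation). Cell cycle genes fell in 7 of 26, 15 over the list alone (median -0.38, 2.67e-09, 0.27 with an estimated correlation), and genes of autism risk fell in 3 of 32, 5 over the list alone (1.02e-06, 0.61 with an estimated correlation). PATHET replicate 3 stood apart by a slope on transcript length of -0.321, against -0.0363 to -0.0013 in the others of its group. With it and HOM replicate 6 left out, 0 ribosomal protein, 0 proteasome and 1 oxidative phosphorylation genes rose in PATHET. Without it 30 genes passed, 7 higher and 23 lower, without WT replicate 2 497, without WT replicate 4 613, without WT replicate 5 737 and without WT replicate 3 782. Within batches 1263 and 16 genes passed, and 55 passed with only 1mo libraries.

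H19, Igf2bp1, Igfbpl1 and Hbb-y fell in all 3 mutants at 1mo. The share of embryonic transcripts, scaled by their level at E14.5, was 1.79% to 2.63% in WT libraries at 1mo and 1.08% to 1.51% in the other libraries of that age. After correction for this share H19 lay at -1.62 in HOM (adjusted p = 0.0019), -0.77 in MATHET (0.41) and -0.40 in PATHET (0.6), and Mki67 lay at -0.37, -0.07 and -0.40. Before the correction H19 fell by similar amounts in the 3 mutants. The share reached 1.51% in HOM, 1.28% in MATHET and 1.27% in PATHET, and a larger share takes more from H19. A loss of H19 particular to HOM therefore does not follow. The cell cycle list then had medians of 0.03, 0.06 and 0.06 and did not pass (camera adjusted p = 0.841, 0.675 and 0.895). Smim3 in HOM was 0.99 after the correction.

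**Figure D4:**
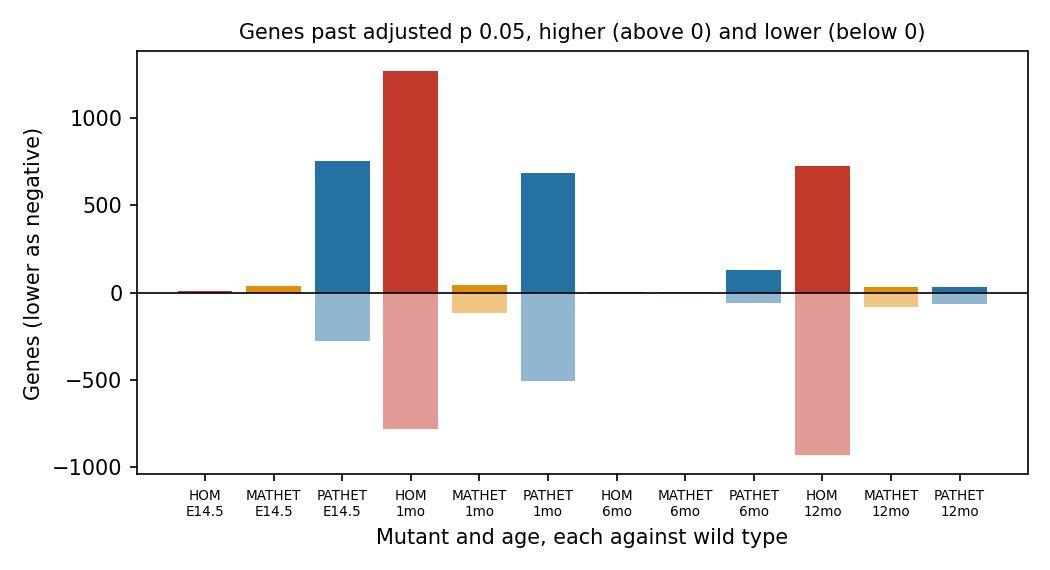
Genes past adjusted p 0.05 for each mutant against WT at each age, with higher genes above 0 and lower genes below.

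At 6mo, HOM cortex differed from WT in 7 genes. Per2 rose from 722±92 to 1190±96 counts (0.72±0.13, limma adjusted p = 0.0102), the immediate early gene Egr1 from 6440±1700 to 10900±2700 (0.75±0.16, 0.0431), and Adipor2, an adiponectin receptor gene, by 0.30±0.06. Cldn5 fell from 879±70 to 580±92 counts (-0.61±0.13), Robo4 fell by 0.89±0.19, Mmp14 fell by 0.54±0.10 (0.0157) and Stoml3 fell by 1.68±0.36 (0.0431), each in 6 of 6 libraries. Counts at an unadjusted p under 0.05 were 1463. No glucocorticoid gene passed over all genes, while 6 rose and 1 fell over the list alone (median 0.32, camera adjusted p = 1.39e-08, 0.023 with an estimated correlation). Circadian genes rose in 1 of 17 members, 4 over the list alone (median 0.21, 2.52e-09 and 0.007). Immediate early genes rose in 1 of 22, 9 over the list alone (median 0.41, 1.65e-12, 0.11 with an estimated correlation). Within batches 3 and 26 genes passed, and with only 6mo libraries 23. Without WT replicate 5 the count was 0, and after the correction for RNA of another age it was 2.

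MATHET cortex at 6mo differed from WT in 2 genes. Pald1 fell from 283±18 to 222±23 counts (-0.35±0.07, limma adjusted p = 0.0439, 6 of 6 libraries), and Gm11240 rose by 0.47±0.09 near the floor (0.0439, 5 of 6). Next in order, and not past the threshold, were Dab1, an adaptor gene of neuronal migration, at -0.32±0.07 (0.145), Olfm5 at -1.22±0.28 (0.21) and Ppp2r2a at 0.14±0.03 (0.21). At an unadjusted p under 0.05 there were 1420 genes. Progenitor genes had 3 falls of 23 over the list alone (median -0.13, camera adjusted p = 1.98e-08, 0.11 with an estimated correlation) and immediate early genes 1 rise of 22 (median 0.33, 1.98e-09, 0.18 with an estimated correlation). Neither list held a member past the threshold over all genes, nor did the glucocorticoid list (median 0.11, 0.00488, 0.26 with an estimated correlation), with 1 rise over the list alone. Within batches 1 and 7 genes passed, and quantile normalization left 0.

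PATHET cortex at 6mo held 131 rises and 58 falls. Plin4, a lipid droplet protein gene, rose from 34±9.6 to 184±86 counts (2.16±0.37, limma adjusted p = 0.000268), Per2 from 722±92 to 1460±140 (1.02±0.13, 6.68e-07), Hif3a by 1.19±0.24 (0.00202), Egr1 by 0.93±0.16 (0.000289), and Banp, a nuclear matrix protein gene, by 0.81±0.12 (3.05e-05), each in 6 of 6 libraries. Sgk1 rose by 0.73±0.17 and Tsc22d3 by 0.55±0.12. Creb5 fell from 311±48 to 160±32 counts (-0.94±0.15, 9.7e-05), the fibrillin gene Fbn1 fell by 0.71±0.16 and Myct1 fell by 0.83. Glucocorticoid genes rose in 5 of 14, 8 over the list alone (median 0.41, camera adjusted p = 1.32e-11, 0.0031 with an estimated correlation), and circadian genes in 4 of 17, 6 over the list alone, with Bhlhe40 at 0.58±0.10 (median 0.16, 9.3e-10 and 0.0031). Immediate early genes rose in 3 of 22, 9 over the list alone with 1 fall (median 0.55, 7.44e-12, 0.14 with an estimated correlation). Per2 stood at 0.92 and 1.11 in the 2 batches, in which 8 and 95 genes passed. With only 6mo libraries 529 genes passed, and without WT replicate 6 83.

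At 12mo, glucocorticoid and heat shock genes were lower in HOM cortex than in the WT libraries of that age, which also enter the WT step from 6mo. Lcn2 fell from 176±120 to 2.55±3.7 counts (-4.86±0.66, limma adjusted p = 9.77e-08), Plin4 fell from 567±190 to 56±13 (-3.17±0.37, 1.25e-09), Serpina3f fell by 3.14±0.41, Sele fell by 2.49±0.44 and Tmem252 fell by 2.27±0.27, each in 6 of 6 libraries. Alox12 rose from 5.4±2.6 to 21.1±7 counts (1.35±0.21, 3.53e-06), Oacyl by 1.17±0.21 and Il17re by 1.50±0.28 near the floor. Totals were 723 rises and 932 falls. Glucocorticoid genes fell in 13 of 14, and all 14 over the list alone (median -0.92, camera adjusted p = 8.3e-36, 2.6e-08 with an estimated correlation), with Tsc22d3 at -1.30±0.12 (3.94e-13), Sgk1 at -1.53±0.17, Fkbp5 at -1.02±0.11 and Nfkbia at -1.07±0.12. Heat shock genes fell in 13 of 16, all 16 over the list alone (median -0.34, 5.87e-16 and 0.035), with Hspb1 at -1.33±0.25. Immediate early genes fell in 5 of 22 (0.0247, 0.99 with an estimated correlation) and circadian genes in 3 of 17, with Per2 at -0.72±0.13 (0.0105, 0.39 with an estimated correlation). Slc2a1 fell by 1.03±0.11 and Cldn5 rose by 0.54±0.13, while the endothelial list held 3 rises and 4 falls and did not pass (0.996). None of 32 mature interneuron genes changed. Tsc22d3 stood at -0.88 and -1.72 in the 2 batches, in which 416 and 891 genes passed. The count was 1096 without WT replicate 2.

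MATHET cortex at 12mo was also lower in glucocorticoid genes. Plin4 fell to 188±140 counts (-1.92±0.37, limma adjusted p = 0.00218), Serpina3f fell by 2.29±0.41, Lcn2 fell by 2.58±0.66 (0.0418), Tsc22d3 fell by 0.65±0.12 (0.00165), Fkbp5 fell by 0.53±0.11 and Grrp1 fell by 1.05±0.17 (0.000112), each in 6 of 6 libraries. Il17re rose by 1.56±0.28 (0.000746) near the floor, Bcl6b by 0.85±0.18, and Nr4a2, a transcription factor gene, from 1660±370 to 2270±370 counts (0.47±0.11, 0.0197). There were 33 rises and 85 falls, with 2637 genes at an unadjusted p under 0.05. Glucocorticoid genes fell in 4 of 14, and over the list alone in 12 with 1 rise (median -0.48, camera adjusted p = 1.93e-14, 0.001 with an estimated correlation). Immediate early genes rose in 1 of 22, 3 over the list alone (median 0.38, 1.86e-06, 0.48 with an estimated correlation). Within batches 0 and 58 genes passed, with only 12mo libraries 361, without MATHET replicate 2 45 and without WT replicate 3 275.

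PATHET cortex at 12mo held 32 rises and 64 falls. Tmem252 fell from 218±130 to 34.3±9.5 counts (-2.28±0.27, limma adjusted p = 3.48e-08), Lcn2 fell to 8.81±11 (-3.84±0.66, 0.000385), Serpina3f fell by 2.69±0.41, and Asb4, an ankyrin repeat gene, fell from 55±18 to 12.6±5.8 (-1.78±0.31, 0.000409), each in 6 of 6 libraries. Ddit4 fell by 0.66±0.13 (0.00425), Nfkbia fell by 0.52±0.12 and Grrp1 fell by 1.32±0.17. Il17re rose by 1.37±0.28 (0.00431) near the floor and Pus7l by 0.53±0.12. Plin4, in contrast to HOM and MATHET, lay at 0.29 and did not pass. Glucocorticoid genes fell in 4 of 14, 6 over the list alone (median -0.29, camera adjusted p = 6.81e-09, 0.033 with an estimated correlation). No interferon and MHC gene of 24 passed over all genes and 6 fell over the list alone (median -0.23, 1.2e-08, 0.084 with an estimated correlation). Within batches 4 and 253 genes passed, and the count was 32 without WT replicate 2, 240 without WT replicate 1 and 26 with Xist and Y genes as covariates.

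The mean of the glucocorticoid list rose from 9.239±0.037 at 6mo to 10.4±0.21 at 12mo in WT, and stood at 9.572±0.19 and 9.349±0.13 in HOM, 9.416±0.087 and 9.894±0.19 in MATHET and 9.69±0.11 and 10.13±0.066 in PATHET. At 6mo the mutants lay above WT by 0.33±0.08 in HOM, 0.18±0.04 in MATHET and 0.45±0.05 in PATHET. At 12mo the mutants lay below WT, at -1±0.1 in HOM, -0.5±0.12 in MATHET and -0.27±0.09 in PATHET. Batch 1 and batch 2 gave 0.16 and 0.5 in HOM, 0.13 and 0.22 in MATHET and 0.38 and 0.52 in PATHET at 6mo. At 12mo they gave -0.86 and -1.2 in HOM, -0.43 and -0.58 in MATHET and -0.13 and -0.4 in PATHET.

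**Figure D5:**
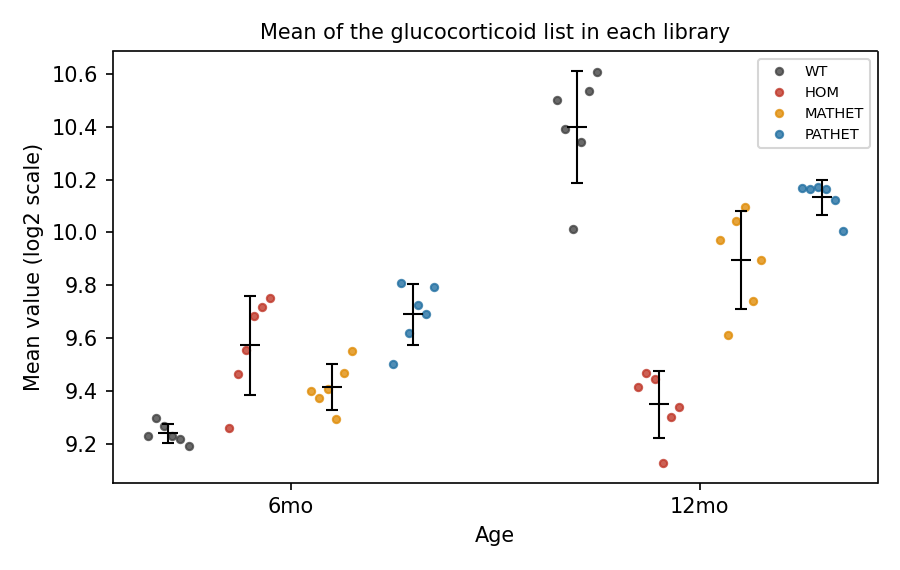
Mean of the glucocorticoid list in each library at 6mo and 12mo.

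Averaged over the 4 ages in HOM cortex, the proliferation gene Mki67 fell by 0.39±0.08 (limma adjusted p = 0.00834), Bub1 fell by 0.58±0.13, and Dlx1 and Dlx2, homeobox genes of interneuron progenitors, fell by 0.28±0.06 (0.017) and 0.29±0.08 (0.0289). Igfbpl1 fell by 0.59±0.11 (0.0032) and Asb4 fell by 0.74±0.16 (0.00742). The transferrin receptor gene Tfrc rose by 0.26±0.05 (0.00333) and Nanp by 0.58±0.13 (0.0149). Totals were 150 rises and 114 falls. Genes of interneuron development fell in 2 of 30, 5 over the list alone (median -0.07, camera adjusted p = 4.59e-05, 0.28 with an estimated correlation), and cell cycle genes in 3 of 26, 9 over the list alone (median -0.14, 9.24e-08, 0.37 with an estimated correlation). After correction for RNA of another age Mki67 lay at -0.25 (adjusted p = 0.12), Bub1 at -0.42 (0.09), Dlx2 at -0.26 (0.068) and Dlx1 at -0.26 (0.03). Within batches 1 and 576 genes passed, with quantile normalization 103 and over 6mo and 12mo alone 149.

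The MATHET average held 9 rises and 13 falls. Ano3, a membrane protein gene of neurons, rose by 0.23±0.04 (limma adjusted p = 0.000642), Mobp by 0.36±0.07 (0.00414) and Tmod4 by 0.63±0.13. H19 fell by 0.62±0.13 (0.0124), Igfbpl1 fell by 0.61±0.11 (0.00375), Mki67 fell by 0.37±0.08 (0.0373) and Sox11, a gene of immature neurons, fell by 0.29±0.06 (0.0124). No progenitor gene passed over all genes and 5 of 23 fell over the list alone (median -0.09, camera adjusted p = 3.5e-09, 0.13 with an estimated correlation). After correction for RNA of another age 3 genes passed, with H19 at -0.31 (adjusted p = 0.62), Igfbpl1 at -0.34 (0.31), Mki67 at -0.19 (0.49), Sox11 at -0.11 (0.55), Mobp at 0.15 (0.83) and Ano3 at 0.14 (0.21). Over 6mo and 12mo alone 7 genes passed and Mobp lay at -0.18.

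The PATHET average held 192 rises and 260 falls. Mobp rose by 0.49±0.07 (limma adjusted p = 4.84e-06), Gfap by 0.50±0.09 (0.000916) and Plp1 by 0.32±0.05. Mcm3, a replication gene, fell by 0.34±0.07 (0.00197), Sox6 fell by 0.17±0.04 (0.006), H19 fell by 0.57±0.13 (0.00551) and Igf2bp1 fell by 0.62±0.13. Cell cycle genes fell in 8 of 26, 15 over the list alone (median -0.20, camera adjusted p = 3.71e-14, 0.13 with an estimated correlation). Progenitor genes fell in 2 of 23, 12 over the list alone (median -0.16, 4.94e-08, 0.13 with an estimated correlation), and myelin genes rose in 6 of 23 (2.72e-06, 0.3 with an estimated correlation). Over 6mo and 12mo alone 71 genes passed, with Mobp at -0.01, Gfap at -0.03 and Plp1 at -0.03. After correction for RNA of another age 205 genes passed, with H19 at -0.23 (adjusted p = 0.62) and Igf2bp1 at -0.23 (0.57), and within batches 28 and 106.

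MATHET and PATHET cortex, which differ in the parent that gave the allele, were compared directly. At E14.5 Ptgds was lower in MATHET, at 141±22 against 394±200 counts (-1.32±0.26, limma adjusted p = 0.0035), as were Plp1 at -0.56±0.10 (0.000581), Mbp at -0.45±0.09, Ntsr2 at -0.79±0.12 (2.8e-05) and S100b at -0.76±0.14. The glycolysis genes Ldha and Pfkl were higher, by 0.32±0.07 (0.0187, 5800±1100 against 4580±150 counts) and 0.26. Totals were 11 rises and 123 falls. Myelin genes were lower in 4 of 23, 16 over the list alone (median -0.43, camera adjusted p = 7.88e-12, 0.096 with an estimated correlation). With only E14.5 libraries no gene passed, and after the correction for RNA of another age 60 did. The count was 49 without MATHET replicate 1 and 613 without MATHET replicate 2.

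At 1mo limma called 0 genes between MATHET and PATHET, with 2164 at an unadjusted p under 0.05. The smallest p-values belonged to 9230104L09Rik at -1.63±0.32 (adjusted p = 0.0605), the MHC gene H2-D1 at -0.41±0.09 (0.178) and the clotting factor gene F5 at 2.09±0.47 (0.21). Choroid plexus genes passed in 14 of 18 members over the list alone and in 0 over all genes (median 1.27, camera adjusted p = 3.25e-14, 0.21 with an estimated correlation). At 6mo 12 genes were higher and 11 lower in MATHET. Creb5 stood at 282±37 against 160±32 counts (0.81±0.15, adjusted p = 0.00981), Fbn1 at 0.79±0.16 and Hunk at 0.57±0.11. Banp stood at 364±60 against 656±96 counts (-0.84±0.12, 3.08e-05, and -0.82 and -0.86 in the 2 batches) and Per2 at -0.63±0.13 (0.0169). With only 6mo libraries 89 genes passed, within batches 0 and 8, and with each library left out in turn 8 to 36.

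At 12mo 89 genes were higher and 102 lower in MATHET than in PATHET. Plin4 stood at 188±140 against 690±210 counts (-2.21±0.37, limma adjusted p = 0.000714), Hif3a at -0.99±0.24 and Fkbp5 at -0.45±0.11 (0.0185). Asb4 stood at 54.6±41 against 12.6±5.8 counts (1.58±0.31, 0.0041), S100a9 at 1.48±0.35 (0.0181), the clock gene Per1 at 0.55±0.12 (0.0117) and Nr4a2 at 0.51±0.11. Immediate early genes were higher in 4 of 22, 15 over the list alone (median 0.57, camera adjusted p = 3.65e-11, 0.44 with an estimated correlation). Within batches 2 and 185 genes passed, with Xist and Y genes as covariates 15, with only 12mo libraries 88 and without MATHET replicate 5 21.

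Differences between mutants and WT varied with age in 1991 genes (limma F test), which does not tell genotype from other differences between the groups. Gpr37l1 (adjusted p = 1.99e-19), Mobp (1.27e-18), Plp1 (4.4e-15), Mal (8.88e-13) and Extl1 (1.45e-12) were higher in MATHET and PATHET at E14.5. Postnatal transcripts at that age may come from an admixture. After the correction for RNA of another age Gpr37l1 in PATHET at E14.5 lay at -0.13. The WT levels of Gpr37l1 meet the rule for genes that set the share, so this value is no separate test. Adipor2 (3.56e-16), the lipid transporter gene Mfsd2a (6.68e-15), Gpt2 (1.48e-14), Tsc22d3 (1.73e-13) and Plin4 (1.41e-12) lay above WT at 6mo and below it in HOM and MATHET at 12mo. Tsc22d3 stood at 0.50, 0.23 and 0.55 in HOM, MATHET and PATHET at 6mo and at -1.30, -0.65 and -0.32 at 12mo. Mfsd2a stood at 0.33, 0.11 and 0.50 at 6mo and at -1.22, -0.71 and -0.01 at 12mo. Within batches 222 and 1467 genes passed.

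Mutants of an age were compared with the same WT libraries, so their differences share an error. Overlaps were set against simulations with that error alone, in which the highest overlap was 0 genes. Those simulations held no genotype effect and drew noise for each gene on its own. Few genes could pass in them, so an overlap of 0 gives the shared counts no support. Error that many genes share was also absent from the simulated r and covariance. At 1mo HOM and PATHET shared 563 rises (41.7 in independent lists) and 306 falls (18.8), with r = 0.704 against 0.501 simulated and a covariance of 0.0316 against 0.0138, a difference of 0.0177. With the WT libraries divided between the mutants, r was 0.408 and 0.434 and 46 and 34 genes were shared. HOM and MATHET shared 36 rises (2.61) and 80 falls (4.4), with r = 0.624 against 0.502, a covariance of 0.026 against 0.0139 (difference 0.0122), and 0.358 and 0.317 with 16 and 19 genes on divided WT libraries. MATHET and PATHET shared 31 rises (1.41) and 76 falls (2.84), with r = 0.578 against 0.5, a covariance of 0.0228 against 0.0138 (difference 0.00899), and 0.254 and 0.32 with 16 and 11 genes on divided WT libraries. H19, Igf2bp1, Igfbpl1 and Mki67 were among the falls of all 3. After correction for the share of embryonic transcripts H19 passed only in HOM, whose libraries reached the highest estimated share among the mutants. With that correction HOM and PATHET shared 780 rises and 151 falls, HOM and MATHET 45 and 18, and MATHET and PATHET 38 and 17. With HOM replicate 6 and PATHET replicate 3 left out, HOM and PATHET shared 23 rises and 35 falls (r = 0.621, covariance 0.0256), HOM and MATHET 118 and 121, and MATHET and PATHET 16 and 34.

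MATHET and PATHET at E14.5 shared 36 rises (1.4 in independent lists), among them Mobp, Gfap and Mag, and 4 falls (0.0532). Their r was 0.571 against 0.547 simulated and their covariance 0.0219 against 0.0166, a difference of 0.00526, with r = 0.208 and 0.215 and 18 and 23 shared genes on divided WT libraries. HOM and PATHET at this age shared 6 rises (0.287) and 2 falls (0.0532), with r = 0.634 against 0.545, a covariance of 0.0254 against 0.0165 (difference 0.00892), and 0.269 and 0.272 with 2 and 1 genes on divided libraries. HOM and MATHET shared 1 rise (0.0149) and 1 fall (0.000763), with r = 0.603 against 0.547, a covariance of 0.0176 against 0.0166 (difference 0.000997), and 0.16 and 0.152 with 1 and 0 genes on divided libraries.

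HOM and MATHET at 12mo shared 21 rises (1.14 in independent lists) and 73 falls (3.78), among them Lcn2, Plin4 and Tsc22d3. Their r was 0.571 against 0.502 simulated, their covariance 0.0294 against 0.0138 (difference 0.0155), and divided WT libraries gave 0.244 and 0.0808 with 73 and 11 genes. HOM and PATHET shared 21 rises (1.1) and 45 falls (2.85), with r = 0.555 against 0.5, a covariance of 0.0273 against 0.0138 (difference 0.0135), and 0.174 and 0.0915 with 41 and 7 genes on divided libraries. MATHET and PATHET shared 2 rises (0.0504) and 12 falls (0.26), with r = 0.542 against 0.501, a covariance of 0.0226 against 0.0138 (difference 0.00885), and 0.0298 and 0.115 with 1 and 5 genes on divided libraries. At 6mo only HOM and PATHET shared genes, 3 rises (0.0188) that included Per2 and Egr1, with r = 0.604 against 0.5, a covariance of 0.02 against 0.0138 (difference 0.00626), and 0.0984 and 0.192 with 3 and 1 genes on divided libraries. HOM and MATHET at 6mo gave r = 0.63 against 0.499 and a covariance of 0.0192 against 0.0137 (difference 0.00545), with 0.14 and 0.127 on divided libraries. MATHET and PATHET at 6mo gave r = 0.552 against 0.499 and a covariance of 0.0186 against 0.0137 (difference 0.00482), with 0.0625 and 0.164 on divided libraries. No gene passed in opposite directions in any pair.

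Over the 19 genotype contrasts 261 of 646 list tests passed with camera at the preset correlation, 13 with an estimated correlation and 74 with fry. Lists that passed with an estimated correlation were myelin in MATHET and PATHET at E14.5, mature interneuron, precursor and astrocyte genes in PATHET at E14.5, and glucocorticoid genes in HOM and PATHET at 6mo and in all 3 mutants at 12mo. The remaining ones were circadian genes in HOM and PATHET at 6mo and heat shock genes in HOM at 12mo. Neither list of interneuron genes passed that test in MATHET or HOM at any age.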

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

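All tests in this part were chosen only after the results were seen, except the test of the list calls over the genotype contrasts. Ube3a in PATHET replicate 3 at 1mo stood at 11.2, against 11.6 to 11.7 in the other libraries of its group, and Ube3a in WT replicate 1 at 12mo stood at 11.8, against 11.6. Xist in HOM replicate 4 at 6mo stood at 9.67, against 2.95 to 3.4 in the rest of that group. The mean of the myelin list in MATHET replicate 5 at 6mo was 11, against 10.7 to 10.8. The mean of the glucocorticoid list in PATHET replicate 6 at 12mo was 10, against 10.1 to 10.2, and the mean of the ribosomal protein list in PATHET replicate 3 at 1mo was 11.5, against 11 to 11.1. Reads in genes of PATHET replicate 4 at 12mo were 14.3 M, against 24.5 to 28.9 M. Slopes on transcript length were -0.263 in HOM replicate 6 at 1mo, against -0.0685 to 0.0257, and -0.321 in PATHET replicate 3 at 1mo, against -0.0363 to -0.0013. These were 9 values standing apart in 7 libraries, with PATHET replicate 3 at 1mo named 3 times, in 128 tests of a group over 8 measures, of which about 1 in 20 would stand apart by chance.

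Differences from WT that varied most between ages had adjusted interaction p-values (limma F test) of 1.99e-19 for Gpr37l1, 1.27e-18 for Mobp and 3.56e-16 for Adipor2. Next were Plp1 (4.4e-15), Mfsd2a (6.68e-15), Gpt2 (1.48e-14), Tsc22d3 (1.73e-13), Mal (8.88e-13), Plin4 (1.41e-12) and Extl1 (1.45e-12).

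Other splits of the libraries asked whether chance could account for each count. It could for HOM at E14.5 (12 genes, highest other split 2822, 65 of 100 splits as large). It also could for MATHET at E14.5 (43, highest other 2516, 16 of 100) and MATHET at 6mo (2, highest other 5, 7 of 100). For MATHET against PATHET at 1mo (0, highest other 8, 100 of 100) every split is as large by definition, so the splits decide nothing there. For HOM and MATHET at E14.5 the highest splits called many times the real count, so those libraries differ from each other along lines other than genotype. The real count exceeded every other split, at 1 of 100, for PATHET at E14.5 (1032, highest other 876) and HOM at 1mo (2052 and 806). So it did for MATHET at 1mo (161 and 51) and PATHET at 1mo (1191 and 175). PATHET at 6mo (189 and 37) and HOM at 12mo (1655 and 552) stood alike. The same held for MATHET against PATHET at 6mo (23 and 3) and 12mo (191 and 176), the HOM average (264 and 60), the PATHET average (452 and 6) and the interaction (1991 and 269). It held as well for the WT steps to 1mo (14689 and 14008), 6mo (2524 and 992) and 12mo (2223 and 657). At 2 of 100 stood HOM at 6mo (7, highest other 10), PATHET at 12mo (96 and 172) and the MATHET average (22 and 145), and at 3 of 100 stood MATHET at 12mo (118 and 135) and MATHET against PATHET at E14.5 (134 and 556). In these 5 the highest split called more genes than the real one. The 261 list calls exceeded the highest other split, with 230 and a median of 170 over the splits, at 1 of 100. A value of 1 of 100 is the smallest these splits can give, and the tests were not adjusted for their number. These splits therefore do not exclude chance for any single count. For the WT step to 1mo limma called 14689 of 20959 genes with a smallest adjusted p of 6.81e-84, which argues against chance for that count.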

How the results depend on the processing

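Alternatives fixed before the data were examined come first here, and 5 were added only after the results were seen: the correction for RNA of another age, 2 length-trend libraries left out, the length trend removed, the average over 6mo and 12mo only, and the glucocorticoid covariate. Counts under an alternative are given where they moved by over 1.5 times, rises and falls where their balance moved, and ranges for every contrast whose libraries were left out. Which property of the libraries moved a count was not tested.

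With only the libraries of an age, counts were 0 in HOM, 1 in MATHET and 26 in PATHET at E14.5, 448, 93 and 55 at 1mo, and 23, 7 and 529 at 6mo. At 12mo they were 361 in MATHET and 61 in PATHET, and for MATHET against PATHET 0 at E14.5, 89 at 6mo and 88 at 12mo. With quantile normalization they were 24 in HOM at E14.5, 2 in HOM and 0 in MATHET at 6mo, 103 in the HOM average, 13 in the MATHET average and 78 for MATHET against PATHET at E14.5 (22 higher and 56 lower). The HOM average then held 47 rises and 56 falls, HOM at E14.5 13 and 11, and the WT step to 1mo 6606 and 8204. Without the lowest 25% of genes 1 gene passed in MATHET at 6mo. With the replicate number as a block in place of the batch term only MATHET against PATHET at 1mo moved, from 0 to 1.

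Batch 1 alone gave 115 in MATHET and 496 in PATHET at E14.5, 16 in HOM and 17 in MATHET at 1mo, 3, 1 and 8 in HOM, MATHET and PATHET at 6mo, and 416, 0 and 4 at 12mo. Its averages gave 1 in HOM, 1 in MATHET and 28 in PATHET, and MATHET against PATHET gave 47 at E14.5, 2 at 1mo, 0 at 6mo and 2 at 12mo. The WT steps to 6mo and 12mo gave 1015 and 316 and the interaction 222. Batch 2 alone gave 601, 21 and 138 in HOM, MATHET and PATHET at E14.5, 62 in MATHET and 16 in PATHET at 1mo, 26, 7 and 95 at 6mo, and 891, 58 and 253 at 12mo. Its averages gave 576, 7 and 106, MATHET against PATHET at 6mo 8, and the WT steps 1068 and 1337. Tsc22d3 in PATHET at 1mo lay at -0.0626 in batch 2. Xist and Y genes as covariates gave 2 in HOM at 6mo, 26 in PATHET at 12mo, 49 in the MATHET average, 262 in the PATHET average and 15 for MATHET against PATHET at 12mo. Of list calls, 13 passed with camera at an estimated correlation and 74 with fry.

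Correction for RNA of another age gave 9 in MATHET and 518 in PATHET at E14.5, 87 in MATHET at 1mo, 2 in HOM at 6mo, 3 in the MATHET average, 205 in the PATHET average, and 60 at E14.5 and 1 at 1mo for MATHET against PATHET. Genes high at 1 age and low at the other set the share, so turns of such genes are no separate test. The correction turned Ntsr2 in MATHET at E14.5 to -0.22. In PATHET at E14.5 it turned Gpr37l1 to -0.13, Lamp5 to -0.54, Camk2a to -0.00974, S100b to -0.50, Egr1 to -0.14, Egr4 to -0.26, C4b to -0.23 and Scn4b to -2.18 (adjusted p = 9.4e-07). At 1mo it turned Top2a to 0.11 in HOM, 0.11 in MATHET and 0.0614 in PATHET, Neurog2 to 0.0934 in MATHET and Hbb-y to 0.14 in PATHET. In the PATHET average Lamp5 turned to -0.12 and S100b to -0.13, and Hbb-y in the WT step to 6mo to 0.89.

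Leaving out the 2 length-trend libraries gave 1343 in HOM, 336 in MATHET and 67 in PATHET at 1mo and 82 in the MATHET average. Removal of the length trend gave 427 in the HOM and 56 in the MATHET average. Averages over 6mo and 12mo only gave 149 in HOM, 7 in MATHET and 71 in PATHET. In these Mobp turned to -0.18 in MATHET. In PATHET, Gfap turned to -0.0282, Mobp to -0.0053, Lamp5 to -0.0395, Nrgn to -0.075, Plp1 to -0.0256, Mal to -0.00695, Mbp to -0.0451, Ntsr2 to -0.11, Aqp4 to -0.15, S100b to -0.10 and Mki67 to 0.00096.

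The glucocorticoid covariate, which by construction absorbs the difference between groups, gave 0 in HOM, 0 in MATHET and 1 in PATHET at 6mo, 3, 1 and 24 at 12mo, and for MATHET against PATHET 1 at 6mo and 109 at 12mo. It turned Tsc22d3 to -0.0392 in PATHET at 6mo and to 0.0043 in MATHET at 12mo. In HOM at 12mo it turned Ch25h to 0.0681, Sox2 to -0.13, Hes5 to -0.21, Mobp to 0.15, Sox9 to -0.0685, Gjb6 to 0.13, P2ry13 to -0.0107, Cldn5 to -0.0784, Ociad2 to 0.034, Hspa5 to 0.0783, Chordc1 to 0.12, Tsc22d3 to 0.0678, Sgk1 to 0.0647 and Nfkbia to 0.0119.

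Leaving out each library in turn, counts ran from 9 to 111 in HOM, 24 to 63 in MATHET and 369 to 1468 in PATHET at E14.5. They ran from 835 to 2304, 77 to 213 and 30 to 1557 at 1mo, 0 to 10, 0 to 3 and 83 to 212 at 6mo, and 1096 to 1991, 45 to 275 and 32 to 240 at 12mo. For MATHET against PATHET they ran from 49 to 613 at E14.5, 0 to 2 at 1mo, 8 to 36 at 6mo and 21 to 374 at 12mo. For the WT steps they ran from 14399 to 14540, 2113 to 2586 and 1722 to 2506.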

Other observations

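The tests of the 3 patterns in this part were chosen only after the results were seen. In HOM at 12mo Selp, an adhesion gene of activated endothelium, fell by 2.09 and the protease inhibitor gene Timp1 fell by 1.91. The microglial receptor gene P2ry12 rose by 0.37±0.09 in HOM at 12mo, when 3 of 20 microglia genes rose over all genes, and 4 rose and 1 fell over the list alone. Asb4 fell in PATHET at 12mo by 1.78±0.31 and in the HOM and PATHET averages by 0.74±0.16 and 0.70±0.16.

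Postnatal transcripts in MATHET and PATHET libraries at E14.5 could come from RNA or reads of postnatal libraries or from embryos of a later stage. The excess of 45 late genes grew with their WT level at 6mo and 12mo, with a slope of 0.999±0.087 in PATHET and 1.03±0.079 in MATHET. An equal admixture gives a slope of 1. In HOM the slope was 0.598±0.12 over only the 34 genes above WT, so it is not a like comparison. The estimated share of postnatal transcripts was 0.316% to 0.364% in HOM libraries of batch 1 and 0.572% to 0.712% in those of batch 2. Myelin genes carried 1.69 times the share of other late genes in PATHET, 1.94 times in MATHET and 1.44 times in HOM. When the WT level at 1mo was taken the ratios were 0.852, 0.876 and 0.798. After the correction for RNA of another age the cell cycle list in PATHET kept a median of -0.368. Its camera adjusted p was 0.12 with an estimated correlation. At E14.5 the correction subtracts a postnatal profile in which these genes are low, so it could hardly move this list. The list also lay below WT in HOM at E14.5, where it did not pass with an estimated correlation. It therefore does not tell a later stage of the embryos from an admixture, and both stay open. After that correction 518 genes passed in PATHET. Of these 509 had passed before in the same direction, 2 in the opposite one and 7 not at all. The highest other split gave 460, with a median of 15 over the other splits. How much of the 518 remains beyond the admixture is uncertain. Where such RNA or reads would have entered was not tested, and raw reads traced by index could tell.

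The mean of the glucocorticoid list lay above WT at 6mo and below it at 12mo in every mutant, with WT itself rising from 9.239±0.037 to 10.4±0.21, and in MATHET at 6mo the list did not pass with an estimated correlation (0.26). All mutants of an age share its WT libraries, so these signs are not independent of each other. The state of the WT animals alone may not account for it, since mutants at 12mo differed among themselves by up to 13.5 standard errors, with PATHET above HOM by 0.78±0.058. Without use of WT, 1 genotype effect alike at both ages is unlikely, since the difference between HOM and PATHET grew from 0.12±0.09 to 0.78±0.058, a change of 6.23 standard errors, while that between MATHET and PATHET changed by 0.355. Whether genotype acts differently with age or the groups differed in hour or handling before dissection stays open, and hormone levels with hours of collection would tell.

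Small rises of ribosomal, oxidative phosphorylation and proteasome genes at 1mo went with steep slopes on transcript length in 1 library of HOM and 1 of PATHET (-0.263 and -0.321, others within 0.091). Removal of the fitted length trend left at least 0.845 of each list median. Whether the fit removed the trend in full was not tested, so the trend is not excluded. Without that library 835 genes passed in HOM, above the highest other split of 305, and 30 in PATHET, above the highest other split of 15, so neither count rests on that library alone, though most of the count in PATHET did. With both libraries left out the list medians went from 0.206, 0.202 and 0.169 to 0.137, 0.144 and 0.115 in HOM and from 0.183, 0.194 and 0.161 to 0.106, 0.108 and 0.0815 in PATHET. Whether RNA integrity differs in these libraries stays open, and integrity values would test it.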
